A study of Homo sapiens with 6 samples.

How the data were processed

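RNA-seq was carried out on a commercial HEK293 line grown in suspension. HEK293 is an established human embryonic kidney line that carries part of an adenovirus genome and is widely used to make recombinant adeno-associated virus (AAV). Cells were transfected with a pair of plasmids and a polymer reagent so that they made AAV, and were collected 18 h later. Untransfected cultures, given PBS in place of both the plasmids and the reagent, were collected at the same time. There were 3 libraries in each of the 2 groups, 6 in all. Per the labels' protocols, 10000000 cells were taken per sample, and libraries were made from total RNA with a stranded Illumina TruSeq kit and read as 75 nt pairs on a NextSeq instrument. The labels number the replicates 1 to 3 in each group but do not say that they came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

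The deposited table holds TPM per gene and library, that is, transcript abundances corrected for length and scaled to a fixed total, as calculated by the authors. STAR and the GRCh38 genome are named in the submitters' processing notes; the counting tool, its strand setting, the annotation release and the rule by which genes were selected are not given in the sources used here. The table has 18298 rows for 18164 distinct Ensembl IDs. The other 134 rows repeat an ID under another symbol with identical values and were dropped. Over the distinct IDs each library's deposited TPM add up to 1000000, within 1, so the authors scaled over the listed genes alone, after some genes had been left out. TPM keeps no record of how many reads were sequenced, so the depth of each library is unknown and no counting interval can be given. Because the total is fixed, a rise in abundant transcripts lowers the TPM of the rest. Values carry 2 decimals. All 18164 IDs are human Ensembl IDs, and 0 features of plasmid, AAV or adenoviral sequence are listed, so vector transcripts were not analysed here. Symbols were taken by Ensembl ID from a name table, which matched 18139 IDs, and otherwise from the deposited table. Gene types, coordinates, transcript length and GC content came from GENCODE release 29 on GRCh38, in which 17706 IDs have a gene type and 13983 are protein-coding. Genes without a type in that release are counted with the genes that are not protein-coding.

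Genes with at least 1 TPM in at least 3 of the 6 libraries were tested. Values were transformed to log2(TPM + 1), and the groups were compared with limma (version 3.58.1 in R 4.3.3; linear model with group as the only term, empirical Bayes moderation with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low TPM. For groups of genes, 32 lists were drawn up from textbook pathways, complexes and marker genes. The 31 with at least 5 tested members were compared with all other genes by camera in limma with a preset inter-gene correlation of 0.01, and beside it by camera with the correlation estimated for each list. The fry test of limma asked whether the members of a list move, on balance, one way, and its mixed form whether they change in either direction; neither compares the list with other genes. Each family of list tests was adjusted over the 31 lists. Counts of members that pass are given with adjustment over all tested genes and with adjustment over the list alone.

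The genes named in the text were chosen by a rule. It took the 12 protein-coding genes with the largest positive and the 12 with the largest negative log2 fold among genes that passed, had a mean of at least 5 TPM in the higher group and had all 3 values of 1 group above all 3 of the other. For each list it took up to 4 members that passed, by size of change, or the 2 members with the highest TPM where fewer than 2 passed. It further took every feature that is not a human gene, of which there were 0, and the 3 largest positive and 3 largest negative changes among genes that are not protein-coding. Any other gene named was chosen after its values were seen, and this is said where it occurs. Some genes that the rule took are not reported here.

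Alternatives tried were pseudocounts of 0.1 and 5, no filter on low values, a filter of 5 TPM, median-ratio scaling, quantile normalization, rescaling after leaving out mitochondrially encoded genes and the 20 most abundant genes, no variance trend, the replicate number as a block, and leaving out each library in turn. The main test, the gene lists, the rule for named genes and these alternatives were fixed before the data were examined. After the data were seen, 2 alternatives were added. One removed the trend of each library's values with GC content and transcript length. The other left out the library with the highest mitochondrial share in each group. All 10 splits of the 6 libraries into 3 and 3 were also fitted.

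The fit was tested on simulated data for the comparison of transfected with untransfected cells, in which 200 of 16145 genes were changed by known amounts. It recovered 95.0% of genes simulated at a log2 fold of 0.5, 70.0% at -0.5, and 100.0% at 1, 2 and -1, with 13 false calls among 199 calls. Histone genes have near-identical copies, and the authors' counting could split reads among them, so values of single histone genes are uncertain. The same holds for genes that overlap a neighbour, since the strand setting of the counting is not stated; among the genes named below it applies to AP2A1, CHORDC1, CTSA, DHCR7, HSPA8, IGLCOR22-1, MT-ND4L, TP53INP1 and UQCRFS1, and to others marked there. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.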

Results

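Gene expression was measured in 3 libraries of HEK293 suspension cells making AAV, 18 h after transfection, and in 3 libraries of untransfected cells collected at the same time. Of 18164 genes listed, 16013 to 16138 had at least 1 TPM in each transfected library and 15714 to 15873 in each untransfected library. The deposited TPM keep no record of depth. Libraries of the same group were closer to each other (Pearson r of log2(TPM + 1) across genes 0.9918 to 0.9948) than to libraries of the other group (0.9757 to 0.9824). The first principal component held 63.7% of the variance and separated the groups, with scores of -24.4 to -20.7 in transfected and 20 to 25.9 in untransfected libraries. The second held 16.6% and set transfected replicate 1 (13.7) and untransfected replicate 3 (17.6) apart from the other 4 libraries (-12.2 to -5.26). The 13 mRNAs encoded by mitochondrial DNA made up 30.0%, 27.6% and 27.1% of TPM in transfected replicates 1 to 3 and 31.2%, 30.0% and 36.4% in untransfected replicates 1 to 3.

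**Figure D1:**
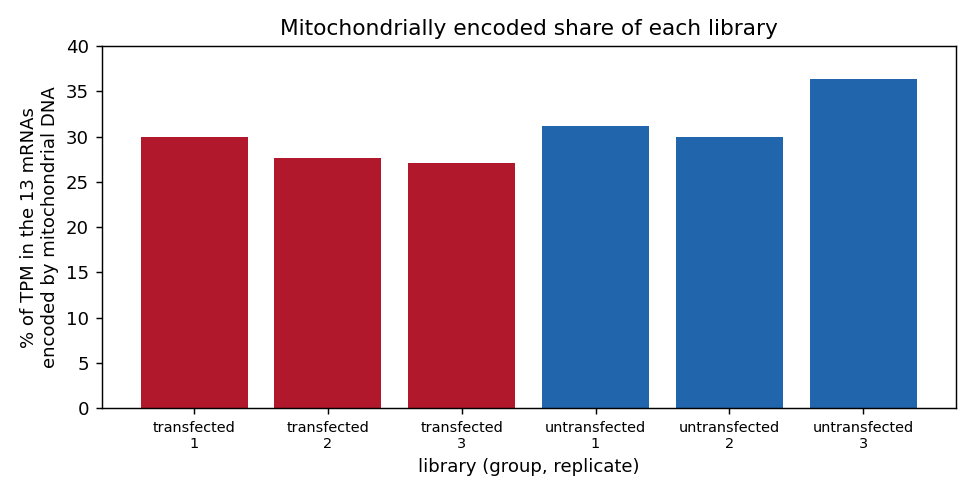
Share of TPM (%) in the 13 mitochondrially encoded mRNAs, 1 bar per library, with transfected libraries in red and untransfected libraries in blue. Untransfected replicate 3 has the highest share, 36.4%.

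The comparison of transfected with untransfected cells asks how the host transcriptome differs during AAV production. The controls lacked both DNA and reagent, so differences cover plasmids, reagent and vector production together. In transfected cells, replication-dependent histone genes had the highest median change of the gene lists, and 36 of 40 ribosome biogenesis genes were higher. Of 33 immediate-early genes 13, EGR1 and ATF3 among them, were higher and 3 lower, and of 26 genes of cholesterol synthesis and uptake 20 were lower and 1 higher. These 4 lists differed from other genes by camera with the preset correlation but not with an estimated correlation (adjusted p = 0.444 for each). Among 16145 genes tested, 3236 were higher and 1644 lower in transfected cells (limma, adjusted p below the threshold of 0.05). Most changes were small, with a median absolute log2 fold of 0.41 among the 4880 genes that passed; 198 genes were at least 2-fold higher and 24 at least 2-fold lower. All 3 values of 1 group lay above all 3 of the other for 46.5% of tested genes, where chance gives 10%.

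The balance of higher and lower calls depended on how libraries were scaled. Of the genes that passed, 66.3% were higher on the deposited TPM, 52.5% after median-ratio scaling (3082 higher, 2789 lower), 50.3% after quantile normalization (2922 and 2887), 52.4% after removal of GC and length trends (3533 and 3209), and 45.9% once mitochondrial and the 20 most abundant genes were left out of the total (2749 and 3241). No gene that passed was called in the opposite direction under any of these. Median-ratio scaling, quantile normalization and the removal of trends centre the libraries on each other. Over all tested genes they gave median log2 folds of -0.005, -0.014 and -0.002, against 0.050 on deposited TPM. Evenness of calls is thus largely built into them, and their percentages do not show whether the excess of higher genes is real. Without transfected replicate 2 the counts fell to 1820 higher and 965 lower, and without transfected replicate 3 to 1873 and 1093; the lower count was 1034 without untransfected replicate 1 and 1086 without untransfected replicate 2. The count at least 2-fold lower was 37 without transfected replicate 3, and 43, 47 and 74 under median-ratio scaling, quantile normalization and without mitochondrial and the most abundant genes. With pseudocounts of 0.1 and 5, 408 and 42 genes were at least 2-fold higher and 89 and 3 at least 2-fold lower, and with the filter of 5 TPM 99 were at least 2-fold higher. With transfected replicate 1 and untransfected replicate 3 both left out, a choice made after the data were seen, 3413 genes were higher and 2098 lower.

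**Figure D2:**
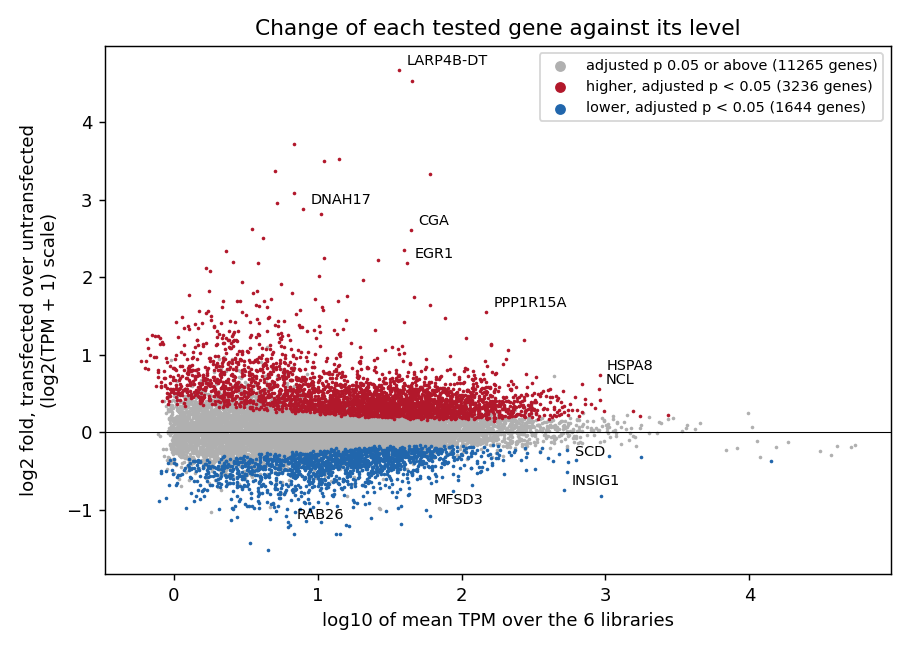
Log2 fold of transfected over untransfected cells on the log2(TPM + 1) scale (vertical axis) against log10 of the mean TPM over the 6 libraries (horizontal axis) for 16145 genes, with 3236 higher genes in red, 1644 lower genes in blue and the 11265 that did not pass in grey. The largest changes are increases and lie below the most abundant genes.

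The protein-coding gene with the largest increase was DNAH17, an axonemal dynein heavy chain gene (ENSG00000187775, GRCh38 chromosome 17, 78423697 to 78577394), at 14.7 ± 0.819 TPM in transfected and 1.13 ± 0.010 TPM in untransfected cells (mean ± SD, n = 3 each here and below), a log2 fold of 2.88 with SE 0.086. CGA (ENSG00000135346, chromosome 6, 87085498 to 87095406), which encodes the common alpha subunit of the pituitary and placental glycoprotein hormones, rose from 11.7 ± 1.23 to 76.7 ± 9.36 TPM, a log2 fold of 2.61. AMH (ENSG00000104899, chromosome 19, 2249309 to 2252073), the gene for anti-Müllerian hormone, rose from 12.3 ± 1.51 to 66.7 ± 7.11 TPM (2.35). EGR1, an immediate-early zinc finger transcription factor (chromosome 5, 138465490 to 138469315), rose from 14.6 ± 2.10 to 69.6 ± 7.25 TPM (2.18). The dehydrogenase gene DHRS2 rose from 3.47 ± 0.326 to 17 ± 1.06 TPM, MEIOSIN, which encodes a meiotic transcription factor, from 1.69 ± 0.273 to 7.86 ± 0.777 TPM, and the stress-inducible GADD45B from 28.4 ± 2.13 to 91.4 ± 10.8 TPM. The remaining 5 of the 12 largest increases with a mean of at least 5 TPM in the higher group were histone genes. Adjusted p of these 12 genes in limma ranged from 4.27e-06 to 0.00115. DNAH17 overlaps PGS1 on the opposite strand, so its values are uncertain.

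The 12 largest decreases among protein-coding genes with a mean of at least 5 TPM in the higher group and no overlap of values between groups were smaller, with log2 folds of -1.20 to -0.91 and adjusted p of 7.30e-05 to 0.00414 in limma. Of the 4 protein-coding genes at least 2-fold lower, TEKTIP1, named after its values were seen, lay below that level, at 4.10 ± 1.63 and 1.39 ± 0.788 TPM in untransfected and transfected cells, and overlaps MFSD12 on the opposite strand. RAB26, a small GTPase of vesicle traffic (chromosome 16, 2140803 to 2154165), went from 9.30 ± 0.754 to 3.50 ± 0.453 TPM. The membrane receptor gene PAQR6 (chromosome 1, 156243321 to 156248117) went from 12.2 ± 1.54 to 5.47 ± 0.306 TPM, and the transporter gene MFSD3 (chromosome 8, 144509074 to 144511213) from 75.9 ± 3.26 to 37.5 ± 1.67 TPM. SLC37A4, the glucose-6-phosphate transporter of the endoplasmic reticulum, went from 48.4 ± 1.97 to 24.0 ± 1.27 TPM. ARSA, the lysosomal arylsulfatase A gene, went from 24.8 ± 1.45 to 12.7 ± 0.785 TPM, and the growth factor receptor gene FGFR3 from 29.9 ± 1.86 to 15.4 ± 0.423 TPM. The other 6 were NRBP2, CRIP3, FBXL8, CCDC78, SYCE1L and MISP3. SLC37A4, CRIP3, FBXL8, CCDC78 and SYCE1L each overlap another gene.

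Replication-dependent histone genes, which encode the bulk of chromatin histones and whose transcripts mostly lack a poly(A) tail, were higher. Of 43 genes on the list 19 were tested, and 18 rose and 0 fell, also when adjusted over the list alone, with a median log2 fold of 1.38. H2BC5 rose from 8.66 ± 1.31 to 44.0 ± 3.15 TPM, H4C5 from 3.28 ± 1.39 to 18.8 ± 2.48 TPM and H1-2 from 21.6 ± 8.04 to 72.0 ± 3.28 TPM. Against all other genes the list stood out by camera with the preset correlation (adjusted p = 1.66e-11) but not with an estimated correlation (adjusted p = 0.444); fry gave an adjusted p of 0.000741. Single histone genes are uncertain because of their near-identical copies.

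Genes of ribosome biogenesis, whose products make and assemble ribosomal subunits in the nucleolus, were higher in 36 of 40 tested, with 0 lower (37 and 0 adjusted over the list alone), and the lowest of the 40 log2 folds was 0.15. RRP12 rose from 25.9 ± 1.18 to 53.7 ± 1.26 TPM (log2 fold 1.02), WDR43 from 105.9 ± 10.3 to 192.5 ± 9.10 TPM (0.86), and RRS1 from 40.5 ± 2.28 to 73.3 ± 4.47 TPM (0.84). The median was 0.47, with adjusted p = 9.32e-16 by camera, adjusted p = 0.444 with an estimated correlation and 0.00192 by fry. Of 69 cytosolic ribosomal protein genes, RPL11 alone passed, at 1599.1 ± 15.9 and 1855.0 ± 25.6 TPM, and 0 passed when adjusted over the list alone. The RPL11 call was lost after median-ratio scaling (adjusted p = 0.0896), without mitochondrial and the most abundant genes (0.138), without GC and length trends (0.216), and when any 1 library other than untransfected replicate 3 was left out (0.0584 to 0.0979). The median of the 69 genes, 0.05, became -0.01 to -0.05 under the 3 other scalings, and the list did not differ by camera (adjusted p = 0.883, and 0.993 with an estimated correlation).

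Immediate-early genes, transcription factors and regulators induced within minutes to hours of a stimulus, were higher in 13 and lower in 3 of 33 tested (16 and 3 adjusted over the list alone). ATF3 rose from 39.9 ± 3.99 to 112.7 ± 8.0 TPM, FOS from 2.41 ± 0.741 to 8.12 ± 0.959 TPM and the synaptic immediate-early gene ARC from 2.66 ± 0.418 to 8.92 ± 1.34 TPM. The list median was 0.16 (camera adjusted p = 0.00416, 0.444 with an estimated correlation, and 0.000741 by fry). Without transfected replicate 3 the median was 0.25, and the lower count was 0 without transfected replicate 2, transfected replicate 3 or untransfected replicate 1 and 1 without transfected replicate 1 or untransfected replicate 2. Of 34 genes of the ATF4 and amino acid response, 13 were higher and 1 lower (13 and 2 adjusted over the list alone), among them PPP1R15A, a regulatory subunit of the phosphatase that acts on eIF2 alpha, at 74.9 ± 2.62 and 221.3 ± 16.6 TPM, ATF4 at 541.6 ± 28.6 and 830.1 ± 13.6 TPM, and the amino acid transporter subunit gene SLC3A2 at 38.3 ± 2.42 and 74.8 ± 3.59 TPM in untransfected and transfected cells. This list did not differ from other genes by camera (adjusted p = 0.210, 0.993 with an estimated correlation), while fry gave 0.0331. Under the 3 other scalings 10 to 11 were higher and 6 to 8 lower. The count was 8 higher without transfected replicate 2, transfected replicate 3 or untransfected replicate 1.

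Heat shock and cytosolic chaperone genes were higher in 13 of 24, with 0 lower, also adjusted over the list alone. HSPA8, the constitutive HSP70 chaperone gene, rose from 684.1 ± 8.15 to 1141.6 ± 29.4 TPM and CHORDC1, a co-chaperone gene, from 34.3 ± 3.61 to 59.4 ± 2.52 TPM. The median was 0.22 (camera adjusted p = 0.00584, 0.993 with an estimated correlation, and 0.0427 by fry); 7 were higher without transfected replicate 2 and 6 without transfected replicate 3. The other 3 scalings gave a median of 0.12 to 0.16 and 1 to 3 lower. Proteasome subunits were higher in 13 of 31, with 0 lower, also adjusted over the list alone, with PSMC3 at 197.2 ± 18.6 and 275.2 ± 13.1 TPM and PSMC4 at 158.7 ± 6.69 and 204.2 ± 3.74 TPM in untransfected and transfected cells. The proteasome list, with a median of 0.19, passed camera (adjusted p = 0.00584), but not with an estimated correlation (adjusted p = 0.993), after quantile normalization (0.0961) or by fry (0.177). Its median was 0.05 to 0.13 under the 3 other scalings and 0.08 without untransfected replicate 3, and 7 and 5 members were higher without transfected replicate 2 and 3. The unfolded protein response of the endoplasmic reticulum had 5 higher and 3 lower of 26 (7 and 3 adjusted over the list alone) and did not differ (camera adjusted p = 0.740, 0.993 with an estimated correlation). The other 3 scalings gave 3 to 5 higher and 4 to 6 lower. With single libraries left out the counts were 2 to 5 higher and 1 to 4 lower, with 2 higher without transfected replicate 3 and 1 lower without transfected replicate 2 or untransfected replicate 2. Among its members XBP1 was at 79.0 ± 9.66 and 108.1 ± 4.58 TPM and WFS1 at 17.7 ± 0.225 and 13.8 ± 0.293 TPM in untransfected and transfected cells.

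Of 21 NF-kB target, cytokine and chemokine genes, 10 were higher and 0 lower, also adjusted over the list alone, with a median log2 fold of 0.35. NFKB1 rose from 13.4 ± 0.773 to 25.8 ± 0.539 TPM and the cytokine gene LIF from 3.95 ± 0.295 to 7.67 ± 0.410 TPM. The chemokine genes had low values, with CXCL11 at 1.52 ± 0.342 TPM in transfected and 0.127 ± 0.110 in untransfected cells, and CCL5 at 1.41 ± 0.299 TPM in transfected cells and listed at 0 in all 3 untransfected libraries. The list passed camera (adjusted p = 0.00584), but not with an estimated correlation (adjusted p = 0.444) or without transfected replicate 1 (0.0562); fry gave 0.000741. Without transfected replicate 2 and 3, 17 and 18 members were tested, of which 6 and 5 were higher, and the median was 0.22 without transfected replicate 3.

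Interferon-stimulated genes moved both ways, with 5 higher and 7 lower of 35, also adjusted over the list alone. IFIT2 (1.70 ± 0.101 and 4.18 ± 0.528 TPM in untransfected and transfected cells), IFIT5 (19.2 ± 2.79 and 29.7 ± 2.82 TPM) and ISG15 (13.9 ± 1.75 and 21 ± 2.71 TPM) rose, and IFITM1 (5.50 ± 0.0608 and 3.06 ± 0.884 TPM) fell; IFIT2 and IFITM1 overlap other genes. The list did not differ from other genes (camera adjusted p = 0.560, 0.993 with an estimated correlation), its median of 0.04 and mean of 0.01 were opposite in sign to the camera direction, and under the 3 other scalings the median was -0.05 to -0.01, with 4 to 5 higher and 9 lower. The adjusted p was 0.823 by fry and 0.000106 by its mixed form, which asks for change in either direction and passed for 28 of the 31 lists. The list of interferons and nucleic acid sensors had 12 members tested, among them sensors and their signalling partners but 0 interferon genes, with 1 higher and 3 lower (1 and 4 adjusted over the list alone). The lower count was 4 to 5 under the 3 other scalings and 1 without transfected replicate 2, transfected replicate 3, untransfected replicate 1 or untransfected replicate 2. IFI16, a DNA sensor, was at 11.5 ± 0.769 and 15.0 ± 1.61 TPM, and MAVS, the adaptor of the RNA sensors, at 57.5 ± 2.24 and 41.2 ± 0.560 TPM in untransfected and transfected cells. The call of IFI16, the higher member, was lost without transfected replicate 2 (adjusted p = 0.0788). Camera gave an adjusted p of 0.0606 for this list and fry 0.00161. The camera value was 0.444 with an estimated correlation, 0.0356 with the filter of 5 TPM and 0.0259 without untransfected replicate 2.

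**Figure D3:**
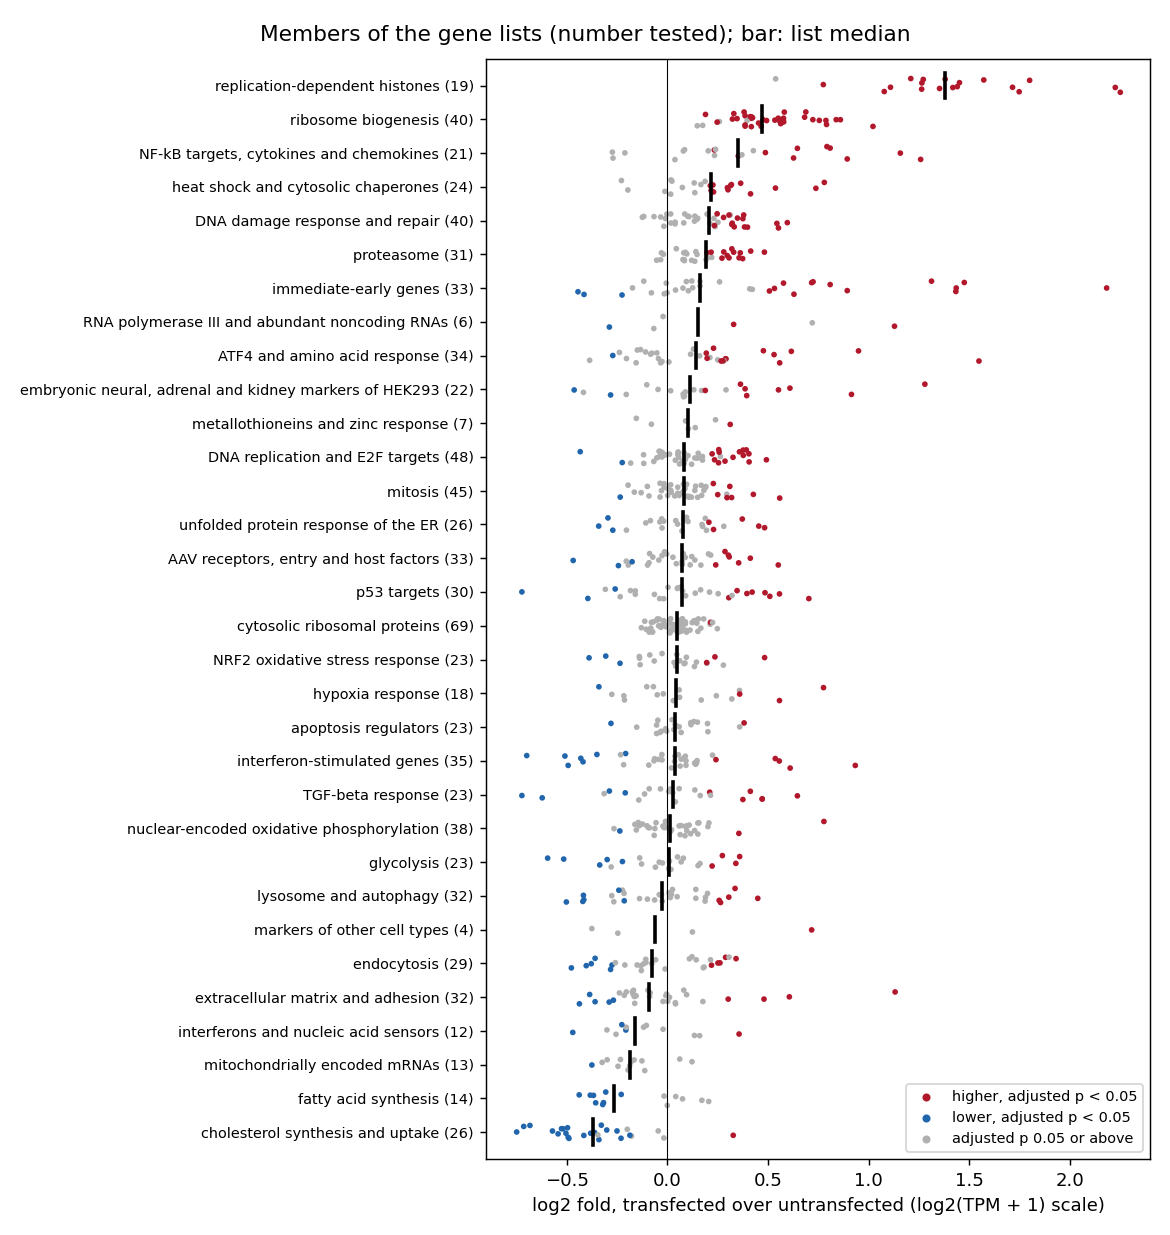
Log2 folds of transfected over untransfected cells (log2(TPM + 1) scale, horizontal axis) of the tested members of 32 gene lists, 1 point per gene, red where higher, blue where lower and grey where the gene did not pass; the black bar is the list median and the number tested stands in brackets. Histone genes have the highest median (1.38) and cholesterol genes the lowest (-0.37), and points are spread vertically for visibility. Some medians near 0, but not all, change sign under other scalings.

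Genes of cholesterol synthesis and uptake were lower in 20 and higher in 1 of 26 tested (21 and 1 adjusted over the list alone), with a median log2 fold of -0.37. INSIG1, the sterol-regulated protein that retains the SREBP processing complex in the endoplasmic reticulum, fell from 647.3 ± 83.7 to 383.9 ± 44.6 TPM. The enzyme genes MSMO1 and DHCR7 fell from 145.7 ± 25.9 to 89.5 ± 6.73 TPM and from 79.2 ± 2.97 to 53 ± 2.17 TPM. The exception was the mevalonate pathway kinase gene PMVK, named after its values were seen, at 50.5 ± 6.41 and 63.3 ± 0.632 TPM in untransfected and transfected cells; 0 were higher without transfected replicate 1, 2 or 3 or untransfected replicate 1. Camera gave an adjusted p of 7.36e-11, the estimated correlation an adjusted p of 0.444, and fry 0.0188. Fatty acid synthesis genes were lower in 8 and higher in 0 of 14 (8 and 1 adjusted over the list alone), with SCD at 618.9 ± 28.4 and 474.1 ± 19.4 TPM and FASN at 289.5 ± 16.1 and 225.8 ± 12.8 TPM in untransfected and transfected cells. For these camera gave an adjusted p of 0.00802, and 0.551 with an estimated correlation, and fry gave 0.0256; the lower count was 4 without transfected replicate 1, and 5 without transfected replicate 2 or untransfected replicate 2.

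DNA damage response and repair genes were higher in 15 of 40, with 0 lower (16 and 0 adjusted over the list alone). MDC1, a scaffold at double-strand breaks, rose from 24.7 ± 0.556 to 37.9 ± 2.23 TPM and RAD51C, of homologous recombination, from 39.5 ± 4.56 to 57.8 ± 1.18 TPM. The median was 0.20 (camera adjusted p = 0.00584, 0.993 with an estimated correlation, and 0.135 by fry), and was 0.10 to 0.14 under the 3 other scalings and 0.12 without untransfected replicate 3. Of its members 5 were higher without transfected replicate 2 or transfected replicate 3, and 9 without untransfected replicate 1. Of 48 DNA replication and E2F target genes, 14 were higher and 2 lower (15 and 2 adjusted over the list alone). MCM10 was at 66.7 ± 2.68 and 94.2 ± 1.65 TPM, RRM2 at 101.9 ± 4.91 and 135.4 ± 5.53 TPM, and E2F1 at 100.3 ± 3.97 and 74.0 ± 4.67 TPM in untransfected and transfected cells. Of 45 mitosis genes 7 were higher and 1 lower (5 and 1 adjusted over the list alone), with PLK1 at 117.4 ± 0.972 and 146.7 ± 5.68 TPM. Of 30 p53 targets 8 were higher and 3 lower (8 and 4 adjusted over the list alone), with GADD45A at 94.8 ± 3.14 and 154.9 ± 2.30 TPM and TP53INP1 at 6.54 ± 0.877 and 3.56 ± 0.478 TPM. None of these 3 lists differed by camera (adjusted p of 0.153, 0.416 and 0.740, and 0.993 each with an estimated correlation), and their medians of 0.08, 0.08 and 0.07 became -0.01 each when mitochondrial and the most abundant genes were left out. Under the 3 other scalings 11 to 13 replication genes were higher and 5 to 8 lower. Likewise 6 to 8 mitosis genes were higher and 3 to 7 lower, and 8 p53 targets were higher and 6 to 8 lower. Without transfected replicate 2 and 3 the higher counts were 9 and 7 for replication, 4 and 4 for mitosis and 5 and 5 for p53. Without untransfected replicate 3 the lower counts were 3 for mitosis and 6 for p53, and the medians 0.02 for replication and 0.00 for mitosis. The lower count of mitosis genes was 0 when any 1 of the other 5 libraries was left out, and that of replication genes 1 without transfected replicate 3 or untransfected replicate 1.

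The 13 mitochondrially encoded mRNAs had a median log2 fold of -0.19, with 1 lower (MT-ND4L, 16109.8 ± 1538.3 and 12397.7 ± 972.8 TPM in untransfected and transfected cells) and 0 adjusted over the list alone. Camera gave an adjusted p of 0.0245 and fry 0.263. The MT-ND4L call was lost after quantile normalization (adjusted p = 0.217), with no filter on low values (0.107), and without transfected replicate 2 (0.101), transfected replicate 3 (0.112), untransfected replicate 1 (0.0699) or untransfected replicate 3 (0.0522). The camera value was 0.993 with an estimated correlation, 0.976 after quantile normalization, where the median was 0.00, and 0.281 without untransfected replicate 3, the library with the highest mitochondrial share. It also missed the threshold without transfected replicate 2 (0.0559) or transfected replicate 3 (0.109), after median-ratio scaling (0.108) and with no filter on low values (0.0968). The same held without GC and length trends (0.102) and without the library of highest mitochondrial share in each group (0.0872). Quantile normalization gives equal ranks equal values, so it can hardly show a change in these mRNAs, which are among the most abundant. Of 38 nuclear-encoded oxidative phosphorylation genes 2 were higher and 1 lower (2 and 0 adjusted over the list alone), with UQCRFS1 at 100.8 ± 5.17 and 129.1 ± 0.820 TPM. Glycolysis had 4 higher and 5 lower of 23, also adjusted over the list alone; the glucose transporter gene SLC2A3 was at 17.6 ± 0.697 and 22.9 ± 1.40 TPM and the aldolase gene ALDOC at 38.6 ± 2.69 and 25.2 ± 2.08 TPM. Hypoxia response genes had 3 higher and 1 lower of 18 (5 and 2 adjusted over the list alone), with VEGFA at 15.3 ± 0.551 and 19.8 ± 0.863 TPM. Their camera adjusted p were 0.740, 0.416 and 0.848, and 0.993 with an estimated correlation. The oxidative phosphorylation median and mean (0.01 and 0.03) and the glycolysis median (0.01, mean -0.04) had the sign opposite to camera, and all 3 medians became negative under the 3 other scalings. There 2 oxidative phosphorylation genes were higher and 6 to 12 lower. Of glycolysis genes 4 were higher and 7 to 9 lower, and of hypoxia genes 3 to 4 were higher and 3 to 4 lower. With single libraries left out, 2 to 4 glycolysis genes were higher and 3 to 5 lower, and without untransfected replicate 3, 6 oxidative phosphorylation and 3 hypoxia genes were lower.

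The next 6 lists did not pass camera. Of lysosome and autophagy genes 5 were higher and 6 lower of 32 (5 and 9 adjusted over the list alone), with GABARAPL1 at 47.2 ± 3.53 and 64.8 ± 0.770 TPM and CTSA at 20 ± 1.13 and 13.8 ± 0.624 TPM in untransfected and transfected cells. Endocytosis genes had 5 higher and 6 lower of 29 (6 and 6 adjusted over the list alone), with AP2A1 at 42.5 ± 0.511 and 30.3 ± 1.56 TPM. The NRF2 oxidative stress response had 3 higher and 3 lower of 23, also adjusted over the list alone. TGF-beta response genes had 6 higher and 4 lower of 23 (6 and 5 adjusted over the list alone), with ID1 at 14.6 ± 1.33 and 8.43 ± 0.289 TPM and ID3 at 114.6 ± 6.46 and 74.1 ± 5.51 TPM. Apoptosis regulators had 1 higher and 1 lower of 23 (0 and 0 adjusted over the list alone), namely CASP8 at 17 ± 1.80 and 22.3 ± 1.21 TPM and BMF at 7.48 ± 0.561 and 5.97 ± 0.339 TPM. BMF lost its call when any 1 of the 6 libraries was left out (adjusted p of 0.0620 to 0.139 in limma), and CASP8 without transfected replicate 2 (0.0620) or 3 (0.0604). Metallothionein and zinc response genes had 1 of 7 higher, SLC30A1, and 0 adjusted over the list alone, a call lost without transfected replicate 2, transfected replicate 3, untransfected replicate 2 or untransfected replicate 3 (adjusted p of 0.0926 to 0.154) and without mitochondrial and the most abundant genes (0.0623). Camera adjusted p for these 6 lists were 0.244, 0.336, 0.765, 0.740, 0.982 and 0.740, and 0.993 with an estimated correlation. The NRF2 and TGF-beta medians and means had the sign opposite to camera, and the NRF2 and apoptosis medians were negative under all 3 other scalings. There 3 to 5 lysosome and autophagy genes were higher and 8 to 11 lower, 3 to 4 endocytosis genes were higher and 10 to 12 lower, and 1 to 2 NRF2 genes were higher and 4 lower. Of the others, 5 to 7 TGF-beta genes were higher and 5 lower, and 1 apoptosis gene higher and 2 lower. With each library left out in turn, 1 to 5 endocytosis genes were higher and 1 to 7 lower, and 3 to 4 lysosome and autophagy genes higher and 4 to 8 lower. The higher count of TGF-beta genes was 2 without transfected replicate 1, 2 or 3 and 3 without untransfected replicate 1, 2 or 3. That of NRF2 genes was 0 without transfected replicate 3 or untransfected replicate 1 and 1 without each other library.

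Extracellular matrix and adhesion genes were higher in 4 and lower in 5 of 32, also adjusted over the list alone, with the collagen gene COL12A1 at 0.877 ± 0.101 and 3.12 ± 0.320 TPM and COL5A1 at 2.28 ± 0.134 and 1.42 ± 0.0252 TPM in untransfected and transfected cells. The COL5A1 call was lost without transfected replicate 3 (adjusted p = 0.0512). Camera gave an adjusted p of 0.0758 (0.783 with an estimated correlation), and of 0.0256 to 0.0409 under the 3 other scalings, where 11 to 12 members were lower; 2 were lower without transfected replicate 2 or 3, 3 without untransfected replicate 1 and 8 without untransfected replicate 3. The camera value was 0.0228, 0.0350 and 0.0460 without transfected replicate 1, transfected replicate 2 and untransfected replicate 1. AAV receptors, entry and host factors were higher in 7 and lower in 3 of 33, also adjusted over the list alone (camera adjusted p = 0.854, 0.993 with an estimated correlation). NCL, the nucleolin gene that is also on the ribosome biogenesis list, rose from 726.5 ± 28.7 to 1065.5 ± 51.0 TPM, and SLC35B2, which carries the sulfate donor into the Golgi, fell from 112.9 ± 2.39 to 81.4 ± 5.68 TPM. The higher count was 2 without transfected replicate 2 and 3 without transfected replicate 3, and the lower count 1 without either of these, untransfected replicate 1 or untransfected replicate 2. Under the 3 other scalings 6 to 7 were higher and 4 to 6 lower.

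Markers of the embryonic neural, adrenal and kidney character of HEK293 were higher in 8 and lower in 2 of 22 (8 and 3 adjusted over the list alone). The granin gene CHGB rose from 2.85 ± 0.424 to 8.33 ± 0.484 TPM and the neurofilament gene INA from 26.9 ± 1.12 to 51.6 ± 2.19 TPM. Camera gave an adjusted p of 0.210 (0.553 with an estimated correlation) and fry 0.000437. With the 3 other scalings 6 to 7 were higher and 3 to 4 lower, and 5 were higher without transfected replicate 3. Of 28 markers of other cell types 4 were tested, and ACTA2, a smooth muscle actin gene that overlaps FAS, rose from 14 ± 1.23 to 23.6 ± 0.308 TPM, the same when adjusted over the list alone; the list was too small for a set test, and its median (-0.06) and mean (0.05) differed in sign. Of 6 genes for polymerase III and abundant noncoding RNAs, 2 were higher and 1 lower, also adjusted over the list alone, with the snoRNA host gene SNHG1 at 100 ± 11.7 and 219.0 ± 12.2 TPM and NEAT1 at 26.0 ± 0.350 and 21.1 ± 1.37 TPM in untransfected and transfected cells (camera adjusted p = 0.740, 0.993 with an estimated correlation). The NEAT1 call was lost without transfected replicate 3 (adjusted p = 0.0549) or untransfected replicate 1 (0.0553), and 1 was higher without transfected replicate 2.

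**Figure D4:**
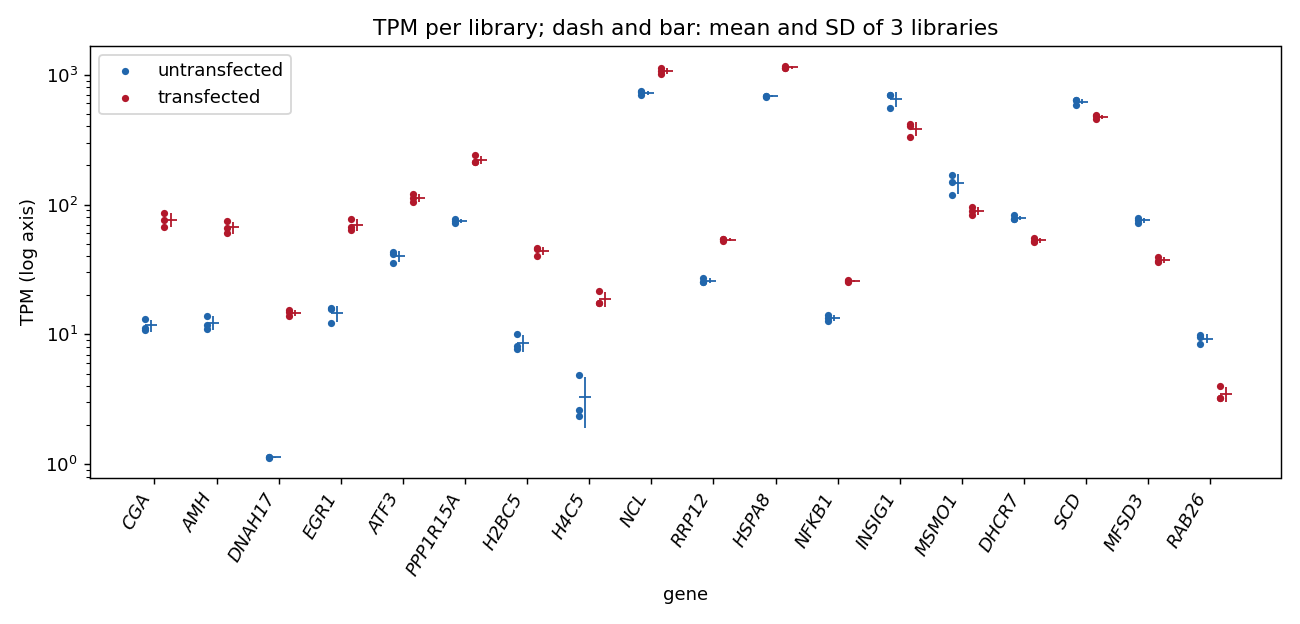
TPM (log axis) of 18 named genes in each of the 3 untransfected (blue) and 3 transfected (red) libraries, with a dash and bar for the mean and SD. All 3 transfected values lie above all 3 untransfected values for the first 12 genes and below them for the 6 from INSIG1 to RAB26.

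Genes that are not protein-coding held the largest changes. LARP4B-DT, a transcript annotated as antisense beside LARP4B (ENSG00000229869, chromosome 10, 933026 to 942743), rose from 1.84 ± 0.444 to 71.8 ± 13.9 TPM (log2 fold 4.68). ENSG00000275468, a processed pseudogene inside BTBD2 on the same strand (chromosome 19, 2013728 to 2014656), rose from 2.88 ± 0.994 to 87.6 ± 11.2 TPM (4.53), and the long noncoding RNA ENSG00000263567 (chromosome 17, 31762440 to 31769048) from 0.117 ± 0.202 to 13.6 ± 1.77 TPM (3.72). Of 3384 such genes tested 601 were higher and 285 lower, against 2635 and 1359 of 12761 protein-coding genes. At least 2-fold higher were 111 of them, 3.28%, and 87 protein-coding genes, 0.682% (Fisher's exact test across genes, two-sided, p = 1.65e-27, with genes not independent of each other). At least 2-fold lower were 20 of them, 0.591%, and 4 protein-coding genes, 0.0313% (p = 1.12e-10 by the same exact test), so these genes were over-represented in both directions. Without transfected replicate 1, 2 or 3 the 111 fell to 66, 61 and 69. In each case 76 of them still passed the filter on low values. The rest reached 1 TPM only in the 3 transfected libraries, so their rise itself brought them into the test and into the 3.28%. The 111 included 35 long intergenic RNAs, 33 antisense RNAs and 20 genes with no type in the annotation used. The 3 largest decreases were ENSG00000286989, which is not in that annotation (7.15 ± 0.346 and 1.86 ± 0.501 TPM in untransfected and transfected cells), IGLCOR22-1, which overlaps RFPL2 on the opposite strand (5.14 ± 0.625 and 1.68 ± 1.67 TPM), and MIR138-1 (18.7 ± 1.84 and 8.28 ± 6.70 TPM). The calls of IGLCOR22-1 and MIR138-1, with adjusted p of 0.0443 and 0.0420 in limma, were lost when single libraries were left out. These were transfected replicate 2 or any untransfected replicate for IGLCOR22-1 (0.0632 to 0.102), and any library other than transfected replicate 1 for MIR138-1 (0.0710 to 0.125).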

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

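The tests without the GC and length trends, and without the library of highest mitochondrial share in each group, were chosen only after the results were seen. No gene that passed was called in the opposite direction under any setting, and 109 of the 137 named genes that passed did so under every setting that tested them. Genes lower numbered 1644 on deposited TPM, 2789 after median-ratio scaling, 2887 after quantile normalization, 3241 without mitochondrial and the 20 most abundant genes, and 3209 without GC and length trends; genes at least 2-fold lower went from 24 to 43, 47 and 74 under the first 3 of these. With pseudocounts of 0.1 and 5, 408 and 42 genes were at least 2-fold higher and 89 and 3 at least 2-fold lower, and 99 were at least 2-fold higher with the filter of 5 TPM. A larger pseudocount shrinks the log2 folds of genes with low TPM, and the filter tests fewer genes. Median-ratio scaling, quantile normalization and trend removal centre the libraries on each other, which by itself evens out higher and lower calls. The shift without mitochondrial and the most abundant genes is weighed below. Leaving out each library gave 1820 to 2955 genes higher, 965 to 2027 lower, 142 to 226 at least 2-fold higher and 27 to 37 at least 2-fold lower, with the fewest genes higher and lower without transfected replicate 2; the 37 came without transfected replicate 3. Camera with the preset correlation called 10 lists, 9 to 11 under the other settings, and 0 with an estimated correlation; 7 of the 10 passed under every setting with the preset correlation, the exceptions being the mitochondrially encoded mRNAs, the proteasome and the NF-kB targets. With the replicate number as a replicate block, 2392 genes were higher and 1137 lower, 197 and 25 at least 2-fold, and 10 lists differed; same-numbered libraries did not deviate together (correlations of -0.184, 0.107 and -0.163), and none of the 3 transfected libraries correlated best with its own number. Sequencing depth is unknown from TPM, so the precision of weakly expressed genes rests on the replicates alone.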

Other observations

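Gene families chosen after the data were seen, 19 in all, were compared with other tested genes by 38 Fisher's exact tests adjusted together, and 5 families passed. These tests take genes as independent, while members of a family can change together, so their adjusted p overstate the evidence. The single genes named for these families were also chosen after their values were seen. DEAD-box and DEAH-box helicase genes, many of which act on ribosomal RNA or mRNA, were higher in 24 and lower in 0 of 47 (adjusted p = 2.61e-05 for the higher count), led by DDX21, which went from 208.1 ± 15.4 to 351.5 ± 17.8 TPM (mean ± SD, n = 3 each). Genes named EIF were higher in 25 and lower in 2 of 52 (Fisher's exact test, adjusted p = 4.93e-05), with EIF3A going from 333.9 ± 14.4 to 492.6 ± 23.2 TPM. They are called translation initiation factor genes here, though the symbol can also take in related genes. Mitochondrial ribosomal protein genes were higher in 34 and lower in 2 of 75 (adjusted p = 1.30e-05), with MRPL58 going from 101.1 ± 6.02 to 191.4 ± 5.19 TPM. The medians of these 3 families were 0.21, 0.22 and 0.19 and stayed positive under all 3 other scalings, at 0.11 to 0.15, where lower members numbered 1 of the helicase, 6 to 8 of the initiation factor and 6 to 8 of the mitochondrial ribosomal protein genes. After removal of GC and length trends 26 helicase genes were higher and 3 lower. The counts were then 25 and 8 for initiation factor genes and 38 and 9 for mitochondrial ribosomal protein genes. The higher count of helicase genes was 15 without transfected replicate 3 or untransfected replicate 1. The lower count of mitochondrial ribosomal protein genes was 6 without untransfected replicate 3. Other families of RNA and protein synthesis did not pass for the higher count, among them RNA polymerase subunits with 9 of 33 higher (adjusted p = 0.411), aminoacyl-tRNA synthetases with 12 of 34 (0.0948), and exosome and RNase P subunits with 7 of 16 (0.0929).

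Zinc finger genes named ZNF were higher in 116 and lower in 10 of 432. Fisher's exact test gave an adjusted p of 0.00326 for the higher count and 9.44e-09 for the lower. ZNF239 went from 18.8 ± 0.886 to 40.3 ± 2.28 TPM. The ZNF median of 0.14 was 0.06 to 0.09 under the other scalings. Without transfected replicate 2, 55 of 430 were higher, beside 1820 of all 15888 tested genes. Without transfected replicate 3, 56 of 430 were higher, beside 1873 of 15901, so the excess was slight in both cases. The lower count of ZNF genes was 24 to 35 under those scalings, 20 without untransfected replicate 3, and 6 without transfected replicate 2, transfected replicate 3 or untransfected replicate 1. After removal of GC and length trends 137 ZNF genes were higher and 41 lower. Solute carrier genes went more often the other way, with 27 higher and 40 lower of 226 (adjusted p = 0.0101 and 0.00326) and a median of -0.04 that stayed negative under the other scalings (-0.13 to -0.09) but was 0.00 without untransfected replicate 2. Their lower count was 68 to 76 under those scalings, and 26 and 27 without transfected replicate 2 and 3, where 13 and 14 were higher. With GC and length trends removed, 35 solute carrier genes were higher and 73 lower. SLC2A4, the insulin-responsive glucose transporter gene, went from 3.51 ± 0.416 to 1.5 ± 0.420 TPM.

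In the weighing that follows, the tests of scaling, of weak expression, of neighbouring genes, of S phase and of other splits were chosen only after the result was seen. More genes were called higher than lower, 66.3% of those that passed. The fixed total of TPM is a candidate explanation: mitochondrial mRNAs took up to 36.4% of untransfected libraries, and once they and the 20 most abundant genes were left out of the total, 45.9% of the genes that passed were higher, within the range of 40 to 60 that this explanation predicts. With the library of highest mitochondrial share left out of each group instead, the percentage was 61.9, above that range, while mitochondrial mRNAs still took 31.2% and 30.0% of the remaining untransfected libraries against 27.6% and 27.1% of the transfected ones. A real excess of higher genes at 18 h is not excluded, since no measure of total RNA per cell was used here.

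Replication-dependent histone genes were higher, with a median log2 fold of 1.381 (95% interval 1.210 to 1.716). The 95% intervals of medians in this section are sign-based over genes taken as independent, and hold no spread between libraries. The estimated inter-gene correlation was 0.256 for histone and 0.645 for replication genes, so such intervals are too narrow. A larger share of cells in S phase would raise the DNA replication list too, but need not raise it as much as histone genes. The median of that list was 0.084 (0.053 to 0.174), far below the histone median. It was -0.008 after quantile normalization and -0.007 without mitochondrial and the most abundant genes, outside that interval. Since the list need not rise as much as histone genes, a contribution of S phase is not excluded. A bias towards short or single-exon transcripts is argued against by 20 other such genes, with a median of 0.040 (-0.234 to 0.138), although only 7 of the 19 histone genes have that form in the annotation used. After GC and length trends were removed the histone median was 1.329, and all 17 members that passed and had values stayed positive. Changes in histone mRNA processing or turnover in transfected cells, and reads split among near-identical copies, were not tested and may each contribute to the 1.329.

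Genes that are not protein-coding were over-represented among those at least 2-fold higher, 111 of 3384 against 87 of 12761, and also among those at least 2-fold lower, 20 against 4. Without transfected replicate 1, 2 or 3, 76 of the 111 were still tested in each case, and 66, 61 and 69 were at least 2-fold higher. The rest of the 111 reached 1 TPM in the transfected libraries alone, so the filter admitted them through their rise. The excess of genes at least 2-fold higher was not confined to weak expression below a mean of 5 TPM. Levels above 5 TPM were not matched between the 2 classes, so weaker expression of genes that are not protein-coding stays a possible explanation. At a mean of at least 5 TPM in untransfected libraries, 13 of 1359 genes that are not protein-coding and 26 of 10533 protein-coding genes were at least 2-fold higher. The ratio of the percentages was 3.88 (Fisher's exact test, p = 0.000249). At that mean over the 6 libraries, which a rise helps a gene to reach, it was 5.06 (33 and 48 genes, Fisher's exact test, p = 4.32e-11). For genes at least 2-fold lower the ratios were 49.1 in untransfected libraries (19 and 3 genes) and 39.3 over the 6 libraries (16 and 3 genes). These rest on few protein-coding genes, and lower genes reach the untransfected level through their higher group. The nearest protein-coding neighbours within 5 kb, on either strand, were found for 59 of the 111. They had a median log2 fold of 0.131 (95% interval 0.060 to 0.195). Of these neighbours 17 passed as higher and 6 as lower, and the neighbours of the other noncoding features had a median of 0.082. For these 59 a raised nearest neighbour is argued against as the general source of reads running on, but not where the neighbour rose. Reads running on from farther away, or from a gene not itself raised, were not tested. A GC or length trend is argued against, since 80 of 91 kept a log2 fold of at least 1 once it was removed. A larger spread of noncoding features at equal TPM, which could add to both directions, stays open because read numbers are unknown. Reads from the plasmids that align to human sequence also stay open, as the plasmid sequences were not used here, and so does a change of noncoding transcription with transfection, as a hypothesis.

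The fold changes also varied with GC content across genes (Spearman rho -0.242), with a median GC of 46.8% in genes called higher and 57.3% in genes called lower. The deviation of each library from the mean of all 6 varied with GC by a rho of 0.103, -0.433 and -0.270 in transfected replicates 1 to 3 and 0.030, 0.041 and 0.464 in untransfected replicates 1 to 3.

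The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. In 1 of the 10, the real one, there were as many genes higher (3236), lower (1644), at least 2-fold higher (198) and at least 2-fold lower (24), and the highest count of the other splits was 0 in each case. For gene lists past the threshold by camera with the preset correlation, 4 of the 10 splits gave at least the real count of 10, and the highest of the others gave 13. Every other split has libraries of both groups on both sides. Part of the real difference then stays between the sides, and the rest adds to the spread within them. Neither the gene counts nor the list counts of these splits show what chance alone would give.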
